A study of Citrullus lanatus with 30 samples.

How the data were processed

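The series holds 30 RNA-seq profiles of watermelon fruit, 18 of flesh over 6 stages, 6 of 20 DAP flesh labelled Mock or 5_Aza, and 6 of rind. Groups and replicate numbers were taken from the sample titles and ages from the age label. The rind libraries have rind as their source and flesh as their tissue label, and were treated as rind. Per the labels, total RNA was extracted with Trizol, treated with DNase I and made into libraries by standard Illumina protocols, and the series' design text names a HiSeq 2500. The submitters' processing notes name fastp, HISAT2 and SAMtools 1.5. The quantifier, its version and the annotation are not given in the sources used here. The deposited values are FPKM per locus, per the file headers, so the authors had already divided by length and by the library total. Library totals, raw counts and gene names are not in these values, and read depth per library is unknown. At low values, 16.9% to 36.3% of loci shared one ratio between the first 2 replicates of a stage group, a trace of whole reads, against 2.03% to 2.99% in the Mock, 5_Aza and rind groups. Depth was not derived from these ratios, and it stayed unknown for Mock and 5_Aza.

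The 18 stage libraries were written with 6 significant digits and the 12 Mock, 5_Aza and rind libraries with 6 decimals. As a sign of how far the formats differ, 45 loci were at 5 FPKM or more in all 12 libraries with 6 decimals and at 0 in all 12 stage libraries from 5 to 30 DAP, and 1 locus showed the reverse. Comparisons of 5_Aza with Mock, of R2 with R4 and of R4 at 2 ages stayed within one format. Comparisons of rind with flesh crossed formats. The rind libraries also form a later block of sample numbers than all flesh libraries, Mock and 5_Aza included, so tissue and that block cannot be separated.

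Rows were checked for alignment by correlating each library with the others on log2(FPKM + 1). In PD replicate 3 a stray record names gene Cla97C05G108990 at chromosome 5, 35523256 to 35526568, with the value 25.3, which the file lists 1 row above that locus. The 11643 values from there on were moved by 1 row, which raised their correlation with PD replicate 1 from 0.119 to 0.993. In AP replicates 1 and 2 the values did not follow the loci as deposited, where their highest correlation with any of the 28 other libraries was 0.0085 and 0.0077. Moved by 56 rows they correlated with AP replicate 3 at 0.511 and 0.473, and means over 200 rows at 0.995 and 0.995, so the order is displaced and also disturbed within short stretches. A shift of all rows thus did not restore single loci as it did in PD replicate 3. They were used only for per-library summaries, so AP replicate 3 alone stood for 1 DAP. That library lists loci with a start lower by 1, repeats 5 loci and lacks 15. In blocks of 50 rows, values were left out where the best correlation with a library of the same group (or, for AP replicate 3, of the 0 DAP group) was under 0.8. This removed 50 scaffold loci of AP replicate 3 (correlation 0.567) and, in CT replicate 1, 50 loci on chromosome 1 from 28189554 to 28726638 (correlation 0.708). The lowest correlation of a kept block was 0.882. These repairs were chosen after seeing the data. No replicates were duplicates in the 10 groups with at least 2 usable libraries: at least 80.6% of loci differed in value between any 2 libraries of a group.

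Differential levels were tested with limma 3.58.1 in R 4.3.3 (trended, robust empirical Bayes) on log2(FPKM + 1). Loci entered at 1 FPKM or more in at least as many libraries as the smallest labelled group of the fit. One fit took the 16 usable stage libraries (17245 loci, 10 residual degrees of freedom), one the 6 Mock and 5_Aza libraries (15552 loci, 4 degrees of freedom), and one the 12 libraries of 20 and 30 DAP flesh and of rind (16901 loci, 7 degrees of freedom). A single library at 1 DAP was assumed to vary like the other groups, as were the rind groups of 2. P-values were adjusted by Benjamini and Hochberg within each comparison with a threshold of 0.05, and counts with a change of at least 2-fold are given beside. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low loci. At a pseudocount of 0.1, 5 of the 48 log2 fold changes named were over 1.5 times larger. Sets of up to 500 loci were tested with limma's camera (preset correlation 0.01, and estimated) and fry.

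Before the data were examined, the comparisons, tests, alternatives and the rule for named loci were fixed, including lists of genes by product description. The files do not pair loci with descriptions and no reference was used here, so those lists could not be applied, and the rule's provision for that case held. Per comparison, at most 2 loci that rose and 2 that fell were named, those with the largest change among loci past the threshold, with replicates that do not overlap and a mean of at least 10 FPKM in the higher group. For the interaction, overlap of replicates was not checked, and the mean limit applied to the highest of its groups. Alternatives were median-of-ratios scaling, no low-value filter, a pseudocount of 0.1, limma without trend and robust fitting, the 28 usable libraries in one fit, the replicate number as a block, other set sizes, and each library left out in turn on the loci of the full fit. Chosen after seeing the data were rows as deposited, the misaligned blocks kept, the fit without 1 DAP or without PD replicate 3, rind alone, Mock as the reference for rind, the set test of 5_Aza on the 10 to 20 DAP step, the limit on the Mock level in the test of depth, and the tests of loci switched on by 5_Aza.

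The fits and the shift tests were run on simulated data. With 100 loci changed by 1 log2 unit, the fit recovered 89% of them for 5_Aza against Mock, 93% for 30 against 20 DAP flesh, 89% for 1 against 0 DAP, 90% for rind R4 against flesh at 20 DAP and 91% for rind R2 against R4. With changes of 0.5 log2 units the shares were 72%, 71%, 48%, 61% and 50%, and between 4 and 10 unchanged loci were called. The simulated values had independent normal noise with each locus's residual spread around 1 mean shared by all groups, and few loci changed. The shares therefore do not test whether the single 1 DAP library varies like the others. Nor do they cover fits where a large part of the loci change, as in these data. Other computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.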

Results

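Transcript abundance was measured by RNA-seq in fruit of watermelon (Citrullus lanatus) cultivar 97103. Flesh was sampled at 6 stages labelled PD (0 DAP), AP (1 DAP), SW (5 DAP), BW (10 DAP), CT (20 DAP) and RF (30 DAP), with 3 libraries per stage. A second set of 20 DAP flesh held 3 libraries labelled Mock and 3 labelled 5_Aza. The name 5-Aza is commonly used for 5-azacytidine, an inhibitor of DNA methyltransferases, and the labels give no dose or time of treatment. Rind was represented by 2 libraries each of R4_CT (20 DAP), R4_RF (30 DAP) and R2_RF (30 DAP). FPKM were given for 22596 loci, except that AP replicate 3 lacks 15 of them and 1 value of AP replicate 1 is not a number. These loci are named only by coordinates on the sequences WM97pbV1_Chr01 to WM97pbV1_Chr11 and on 23 scaffolds. Loci are therefore given by chromosome, start and end, and what each encodes, and whether a position lies in an exon, an intron or a UTR, was not analysed here.

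Summed FPKM ranged from 762714 in SW replicate 3 to 886495 in CT replicate 3, and 14199 to 16190 loci per library reached 1 FPKM. Read totals are unknown, so no counting interval or detection floor could be given for single values. Replicates of a group correlated at 0.993 to 0.997 on the log2 scale, and the median coefficient of variation at loci of 10 FPKM or more lay between 3.18% in BW and 6.20% in CT. At 1 DAP a single library could be assigned to loci, so values at that stage have n = 1 and no SD. The labels do not say whether replicates came from separate fruits, and the p-values measure only the spread between these libraries, which may be technical.

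The most abundant transcript of the flesh changed with stage. At 0 DAP it came from chr2:2337240-2337639, with 8406 ± 459 FPKM (SD, n = 3), a locus that stood at 6.02 ± 1.88 FPKM at 30 DAP. At 10 and 20 DAP it came from chr10:21559312-21559608, which rose from 25.4 ± 16.6 FPKM at 0 DAP to 34396 ± 1372 at 10 DAP and 99167 ± 18578 at 20 DAP. That locus alone held 11.4 ± 2.30% of the summed FPKM in stage flesh of 20 DAP, and 1.19% at 30 DAP. In Mock flesh, with the same age label of 20 DAP, it was also the highest locus but held 1.55 ± 0.03%. At 30 DAP the highest level was 30735 ± 937 FPKM at chr8:4243307-4243756. These loci were singled out after their values had been seen.

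Across the 6 stages, 16640 of 17245 tested loci (96.5%) differed in at least one stage (limma F test, adjusted p under 0.05), and 12284 of them had a range of stage means of at least 2-fold. Of these 12284 loci, 3447 were highest at 0 DAP, 2223 at 1 DAP, 2027 at 5 DAP, 1088 at 10 DAP, 966 at 20 DAP and 2533 at 30 DAP. The lowest mean fell at 30 DAP for 4229 loci and at 20 DAP for 2579. Means fell at each of the 5 steps for 1200 loci and rose at each for 391. A range of 16-fold or more was reached by 1470 loci, 527 of them highest at 0 DAP and 258 highest at 30 DAP. The counts by stage and by step used FPKM without median-of-ratios scaling. That scaling moved the median log2 fold change of all loci by 0.12 from 5 to 10 DAP and by 0.14 from 10 to 20 DAP. Whether the counts hold under it was not tested, and the values at 1 DAP rest on 1 library. Group means of 0 and 1 DAP flesh correlated at 0.981 across loci, and those of 0 and 30 DAP at 0.757, where loci are not independent replicates.

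The first step, from 0 to 1 DAP, had the fewest 2-fold changes of the 5 steps, and 653 loci were at least 2-fold higher against 135 lower. The locus at chr1:7582115-7583400 rose from 10.3 ± 2.39 FPKM (SD, n = 3) to 299 FPKM (log2 fold change 4.76 ± 0.36 SE, limma adjusted p = 5.73e-07). A short locus at chr10:24792349-24792534 was listed at 0 in all 3 libraries at 0 DAP and at 20.1 FPKM at 1 DAP (limma adjusted p = 0.000207). The reverse held at chr5:32861864-32862096, listed at 0 at 1 DAP and at 14.4 ± 10.6 FPKM at 0 DAP (limma adjusted p = 0.00554). Transcripts of chr4:20893416-20893865 fell from 17.2 ± 4.10 to 2.05 FPKM (log2 fold change -2.56 ± 0.65, limma adjusted p = 0.00555), a call that ended at a pseudocount of 0.1, where the fall was no smaller (log2 fold change -2.99, limma adjusted p = 0.0598). In all, 3601 loci rose and 4890 fell (limma, adjusted p under 0.05). With 1 library at 1 DAP, its spread was assumed to equal that of the other stages. The filter asked for 1 FPKM in 3 libraries, so a locus that reached it at 1 DAP alone could not be counted.

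Between 1 and 5 DAP, 2 loci that were abundant in the youngest flesh fell almost to the floor. At chr3:28841637-28842794 the level was 492 FPKM at 0 DAP and 557 FPKM at 1 DAP, and 0.343 ± 0.074 FPKM at 5 DAP (SD, n = 3, log2 fold change -8.70 ± 0.21 SE, limma adjusted p = 1.62e-12). At chr10:21643784-21644074 it fell from 291 to 0.242 ± 0.210 FPKM (log2 fold change -7.89 ± 0.44, limma adjusted p = 4.89e-09). The largest rise was at chr10:33215489-33219675, from 1.52 to 183 ± 3.90 FPKM (log2 fold change 6.19 ± 0.10, limma adjusted p = 1.39e-13). The locus at chr10:21559312-21559608, the most abundant one of later flesh, rose from 55.6 to 3063 ± 162 FPKM at the same step (log2 fold change 5.76 ± 0.42, limma adjusted p = 6.07e-08). Of all tested loci, 5865 rose and 6353 fell (limma, adjusted p under 0.05), 1883 and 2077 of them by at least 2-fold. The single library at 1 DAP limits this step as it does the previous one.

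From 5 to 10 DAP the locus at chr8:4243307-4243756 rose from 100.5 ± 2.30 to 12280 ± 462 FPKM (SD, n = 3, log2 fold change 6.92 ± 0.11 SE, limma adjusted p = 3.15e-14). A long locus at chr5:5291771-5303347 rose from 0.578 ± 0.111 to 225 ± 2.32 FPKM (log2 fold change 7.16 ± 0.06, limma adjusted p = 1.41e-16). At chr7:2042902-2043252 the level fell from 254 ± 4.69 to 4.36 ± 0.45 FPKM (log2 fold change -5.57 ± 0.25, limma adjusted p = 6.54e-10). The locus at chr9:35684709-35685035 fell from 605 ± 36.7 to 13.5 ± 2.58 FPKM (log2 fold change -5.40 ± 0.30, limma adjusted p = 3.99e-09) and had stood at 1092 FPKM at 0 DAP. More loci fell (7959, of which 1759 by at least 2-fold) than rose (4268, of which 907 by at least 2-fold; limma, adjusted p under 0.05). Median-of-ratios scaling of the libraries moved the median log2 fold change of all loci by 0.12, and 5681 loci then rose and 6343 fell. By at least 2-fold, 1092 then rose and 1390 fell, so much of the excess of falls rests on the scaling.

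The step from 10 to 20 DAP held 3164 changes of at least 2-fold, 863 higher and 2301 lower. The largest rise was at chr6:4794949-4796297, from 6.66 ± 2.21 to 3894 ± 450 FPKM (SD, n = 3, log2 fold change 9.02 ± 0.17 SE, limma adjusted p = 8.57e-14). It was followed by chr7:3768191-3777136, which rose from 3.14 ± 1.25 to 957 ± 39.5 FPKM (log2 fold change 7.90 ± 0.19, limma adjusted p = 8.02e-13) and reached 2797 ± 24.6 FPKM at 30 DAP. At chr10:23682074-23682352 the level fell from 239 ± 13.1 to 1.31 ± 1.33 FPKM (log2 fold change -6.85 ± 0.30, limma adjusted p = 2.89e-10). At chr6:951879-954974 it fell from 253 ± 0.57 to 2.07 ± 0.83 FPKM (log2 fold change -6.41 ± 0.17, limma adjusted p = 2.18e-12). In all, 4274 loci rose and 8039 fell (limma, adjusted p under 0.05). Median-of-ratios scaling moved the median log2 fold change of all loci by 0.14, and 6035 loci then rose and 6393 fell. By at least 2-fold, 1125 then rose and 1946 fell.

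From 20 to 30 DAP, 2 loci with low levels at every earlier stage from 5 DAP on rose more than 100-fold on the FPKM + 1 scale. At chr1:69753-70532 the level rose from 1.43 ± 0.56 to 571 ± 19.0 FPKM (SD, n = 3, log2 fold change 7.91 ± 0.16 SE, limma adjusted p = 2.85e-13). At chr8:3714025-3714591 it rose from 1.37 ± 0.47 to 332 ± 9.97 FPKM (log2 fold change 7.15 ± 0.24, limma adjusted p = 5.04e-11). The locus at chr11:11861823-11863862, at 1605 ± 31.9 FPKM at 10 DAP, fell from 249 ± 28.3 to 3.92 ± 0.51 FPKM (log2 fold change -5.66 ± 0.10, limma adjusted p = 1.16e-13). At chr11:7970524-7970829 the level fell from 41.2 ± 3.18 to 0.193 ± 0.168 FPKM (log2 fold change -5.15 ± 0.24, limma adjusted p = 7.53e-10). Mock flesh, also of 20 DAP, held 0.899 ± 0.732 FPKM at the first fallen locus, under its 30 DAP level, so that fall rests on the stage libraries. It held 4.10 ± 1.77 FPKM at the second. At the 2 risen loci Mock held 6.95 ± 1.03 and 3.43 ± 0.49 FPKM, far under their 30 DAP levels. Of all tested loci, 5743 rose and 4843 fell (limma, adjusted p under 0.05), 907 and 703 of them by at least 2-fold. With median-of-ratios scaling 5268 rose and 5523 fell, 858 and 805 of them by at least 2-fold, so the direction that prevails over all calls rests on the scaling, while rises prevail at 2-fold under both.

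**Figure D1:**
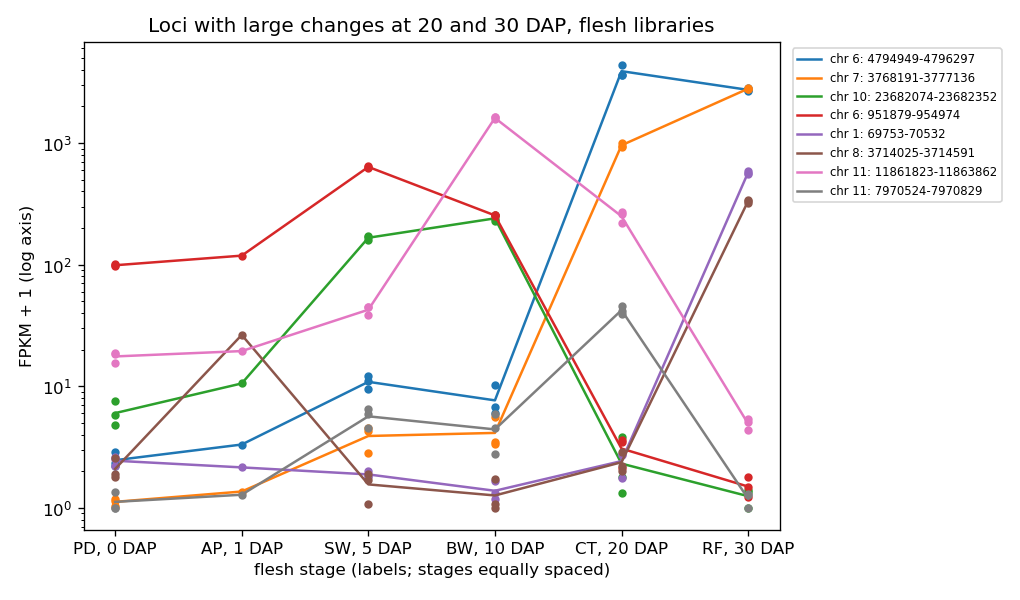
FPKM + 1 on a log axis for the 8 loci named for the 2 last steps of the flesh, against the 6 stages in order (equally spaced), with 1 point per library and lines through the stage means. The loci at chr6:4794949-4796297 and chr7:3768191-3777136 go from stage means of at most 9.88 and 3.14 FPKM up to 10 DAP to means of 3894 and 957 FPKM at 20 DAP, and those at chr1:69753-70532 and chr8:3714025-3714591 reach means of 571 and 332 FPKM at 30 DAP.

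The comparison of 5_Aza with Mock flesh asked which transcripts changed after the treatment at 20 DAP. Changes of at least 2-fold were nearly all rises, 636 loci against 29. A pair of loci on chromosome 2 stood out with the largest rises. At chr2:30433270-30433895 the level was 0.034 ± 0.060 FPKM in Mock and 45.1 ± 5.46 FPKM in 5_Aza (SD, n = 3, log2 fold change 5.47 ± 0.10 SE, limma adjusted p = 1.01e-10). At chr2:30424331-30424897 it was 0.736 ± 0.167 and 68.4 ± 3.04 FPKM (log2 fold change 5.32 ± 0.09, limma adjusted p = 2.71e-11), and this second locus was listed at 0 in every flesh stage and rind library used. The largest fall was at chr2:5131165-5133091, from 25.9 ± 2.47 to 5.55 ± 0.24 FPKM (log2 fold change -2.04 ± 0.08, limma adjusted p = 1.04e-08). It was followed by chr11:7321443-7324127, from 58.5 ± 1.54 to 16.2 ± 0.30 FPKM (log2 fold change -1.79 ± 0.05, limma adjusted p = 6.30e-10).

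Without the 2-fold limit, 4586 of 15552 tested loci rose and 2064 fell after 5_Aza (limma, adjusted p under 0.05). With median-of-ratios scaling 3308 rose and 3479 fell, and the changes of at least 2-fold were 544 rises and 48 falls. The 636 loci that rose by at least 2-fold had a median level of 2.16 FPKM in Mock and 9.56 FPKM in 5_Aza. The log2 fold change of chr2:30433270-30433895 rested on the pseudocount, being 8.47 at 0.1.

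**Figure D2:**
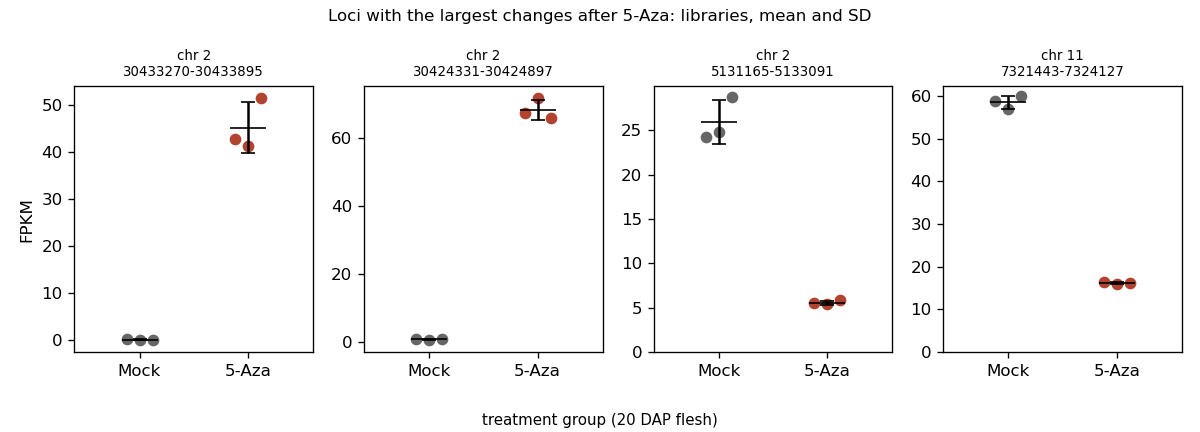
FPKM in each of the 3 Mock and 3 5_Aza libraries of 20 DAP flesh at the 2 loci with the largest rise and the 2 with the largest fall, with the mean (horizontal line) and SD (error bar), each panel on its own axis. The means in 5_Aza are 45.1 and 68.4 FPKM at the 2 risen loci and 5.55 and 16.2 FPKM at the 2 fallen ones. No library of one group lies within the range of the other, which the rule for naming loci required.

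Whether the treated flesh moved along the change from 20 to 30 DAP was tested with 2 sets of 500 loci, those with the smallest p that rose and that fell at that step of the separate stage libraries. Among the 490 measured loci of the risen set, 212 rose and 97 fell after 5_Aza, and the set was not set apart from other loci (limma camera with a preset correlation of 0.01, p = 0.275). Among the 471 measured loci of the fallen set, 228 rose and 87 fell after 5_Aza (limma camera with the same preset correlation, upward, p = 0.0459). That call ended with an estimated correlation (p = 0.396), with 1000 loci per set (p = 0.194), and without Mock replicate 2 (p = 0.0509), Mock replicate 3 (p = 0.0567), 5_Aza replicate 2 (p = 0.0603) or 5_Aza replicate 3 (p = 0.0613). By limma's fry, which allows for correlated loci but does not compare a set with other loci, both sets moved upward, with median log2 fold changes of 0.10 and 0.14 against 0.07 over all loci (p = 0.000217 and 7.39e-05). Median-of-ratios scaling moved the median of all loci by -0.09, a shift of the size of the risen set's median, and fry was not run with that scaling. Across 14689 loci the log2 fold changes of 5_Aza against Mock and of 30 against 20 DAP had a Pearson correlation of -0.012 and a Spearman correlation of -0.0052.

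In 20 DAP fruit, rind R4 was compared with flesh of the same age. Levels in R4_CT exceeded those in flesh by at least 2-fold at 4215 loci and were lower by as much at 1281. At chr5:10117915-10121202 the level was 70.3 ± 5.61 FPKM in rind (SD, n = 2) and 3461 ± 13.2 in flesh (n = 3, log2 fold change -5.60 ± 0.05 SE, limma adjusted p = 3.63e-14). At chr10:31744629-31744958 it was 0.236 ± 0.333 FPKM in rind and 69.6 ± 3.17 in flesh (log2 fold change -5.86 ± 0.16, limma adjusted p = 4.15e-11). The highest rise in rind was at chr9:3608135-3610497, 848 ± 61.3 against 3.32 ± 1.90 FPKM (log2 fold change 7.72 ± 0.35, limma adjusted p = 3.03e-08), but Mock flesh of 20 DAP held 3625 ± 140.5 FPKM there and the log2 fold change against Mock was -2.09. A further locus, chr5:34333334-34334670, was at 145 ± 2.25 FPKM in rind and listed at 0 in flesh (limma adjusted p = 3.63e-14), and it was at 74.6 ± 4.03 FPKM in Mock flesh. In all 8610 loci were higher and 4725 lower (limma, adjusted p under 0.05). Median-of-ratios scaling moved the median log2 fold change by -0.21, giving 7230 higher and 6390 lower, 3529 and 1889 of them by at least 2-fold. The rind, Mock and 5_Aza values carried 6 decimals and the stage values did not, so tissue and number format differ together. Whether the quantification also differed is unknown.

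At 30 DAP the same comparison gave 3063 loci at least 2-fold higher in rind R4 and 1024 lower. Levels at chr7:3379110-3379316 were 2.45 ± 0.16 FPKM in rind (SD, n = 2) and 392 ± 23.7 in flesh (n = 3, log2 fold change -6.83 ± 0.21 SE, limma adjusted p = 1.13e-09). At chr4:1939752-1939973 they were 3.88 ± 0.23 and 428 ± 2.73 FPKM (log2 fold change -6.46 ± 0.23, limma adjusted p = 1.83e-09). Rind was higher at chr4:24619230-24619996, with 502 ± 9.21 against 1.95 ± 0.32 FPKM (log2 fold change 7.42 ± 0.09, limma adjusted p = 4.22e-13), a locus at 358 FPKM in flesh of 5 DAP. The locus at chr9:3608135-3610497 was again higher, with 1540 ± 82.8 against 2.45 ± 1.00 FPKM (log2 fold change 8.85 ± 0.35, limma adjusted p = 1.77e-08), next to the 3625 FPKM in Mock flesh. In all 7638 loci were higher and 4715 lower (limma, adjusted p under 0.05), with a median shift of -0.12 log2 under median-of-ratios scaling and 6605 and 6052 loci then. By at least 2-fold, 2648 were then higher and 1314 lower. The number format again differed between the tissues, and 30 DAP flesh was written in the stage format only.

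Rind R2 at 30 DAP was further from flesh, with 4114 loci at least 2-fold higher and 2617 lower. The loci that rose most in flesh at 20 DAP were nearly silent there, with 2.09 ± 0.31 FPKM at chr7:3768191-3777136 (SD, n = 2) against 2797 ± 24.6 in flesh (n = 3, log2 fold change -9.82 ± 0.06 SE, limma adjusted p = 4.83e-16). At chr6:4794949-4796297 the levels were 4.76 ± 0.37 and 2733 ± 68.0 FPKM (log2 fold change -8.89 ± 0.08, limma adjusted p = 6.37e-15). The most abundant transcript of R2, from chr6:7824799-7825077, was at 34275 ± 488 FPKM against 49.2 ± 1.76 in flesh (log2 fold change 9.42 ± 0.07, limma adjusted p = 6.73e-16). At chr2:5602271-5602603 the levels were 525 ± 10.9 and 0.161 ± 0.140 FPKM (log2 fold change 8.83 ± 0.24, limma adjusted p = 1.10e-10). In all 7773 loci were higher and 6193 lower (limma, adjusted p under 0.05), across the 2 number formats. With median-of-ratios scaling 7428 were higher and 6711 lower, 3915 and 2849 of them by at least 2-fold.

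The 2 rind groups of 30 DAP, written in one format, differed at 3429 loci by at least 2-fold, 1566 higher in R2 and 1863 higher in R4. R4 held 1588 ± 0.31 FPKM (SD, n = 2) at chr7:3768191-3777136 where R2 held 2.09 ± 0.31 (log2 fold change of R2 against R4 -9.01 ± 0.07 SE, limma adjusted p = 2.06e-15). R4 held 2912 ± 38.9 FPKM at chr5:7789664-7791009 against 7.85 ± 0.32 in R2 (log2 fold change -8.36 ± 0.06, limma adjusted p = 2.30e-15). R2 was higher at chr1:525449-526327, with 241 ± 15.9 against 3.11 ± 0.65 FPKM (log2 fold change 5.89 ± 0.12, limma adjusted p = 5.54e-12). It was also higher at chr8:21145219-21145797, with 75.6 ± 0.22 against 0.577 ± 0.364 FPKM (log2 fold change 5.62 ± 0.15, limma adjusted p = 5.27e-11). In all 5146 loci were higher and 6237 lower in R2 (limma, adjusted p under 0.05). With median-of-ratios scaling the counts were 5740 and 5732, and 1693 and 1644 by at least 2-fold, so the excess in R4 rests on the scaling.

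From 20 to 30 DAP, 1309 loci fell and 521 rose by at least 2-fold in rind R4. At chr11:753705-756885 the level rose from 0.018 ± 0.025 to 54.6 ± 2.86 FPKM (SD, n = 2, log2 fold change 5.77 ± 0.10 SE, limma adjusted p = 4.69e-11), a fold change of 8.87 log2 at a pseudocount of 0.1. At chr2:2318647-2319172 it rose from 0.117 ± 0.025 to 45.2 ± 1.81 FPKM (log2 fold change 5.37 ± 0.25, limma adjusted p = 4.97e-08). At chr5:28240188-28241114 it fell from 45.4 ± 2.81 to 0.324 ± 0.249 FPKM (log2 fold change -5.14 ± 0.19, limma adjusted p = 2.06e-09), and at chr8:21133853-21136470 from 56.03 ± 0.46 to 0.623 ± 0.052 FPKM (log2 fold change -5.14 ± 0.12, limma adjusted p = 1.97e-10). In all 4055 loci rose and 4361 fell (limma, adjusted p under 0.05). With median-of-ratios scaling 4350 rose and 4351 fell, and 518 and 1268 by at least 2-fold. Without R4_CT replicate 2, 3908 rose and 3539 fell, so the direction that prevails over all calls rests on a single library.

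With age, the libraries of rind R4 changed in the direction of the earlier change of the flesh from 10 to 20 DAP. Of the 500 loci that had risen in flesh at that step with the smallest p, 407 rose and 35 fell in rind R4 (limma camera with a preset correlation of 0.01, p = 2.74e-35). Of the 475 measured loci that had fallen in flesh, 400 fell and 36 rose in rind R4 (limma camera with the same preset correlation, p = 3.30e-36). Both calls held with an estimated correlation, with p = 0.0142 for the risen set and p = 0.000457 for the fallen set. Examples are chr6:4794949-4796297, at 176 ± 5.29 FPKM in R4 at 20 DAP and 1142 ± 47.3 at 30 DAP, and chr7:3768191-3777136, at 643 ± 16.8 and 1588 ± 0.31 FPKM. Across 15872 loci, which are not independent replicates, the 2 changes had a Pearson correlation of 0.571 and a Spearman correlation of 0.546. No library was shared between them. R2 was sampled at 30 DAP only, so the result covers R4 alone. The rind libraries have rind as their source but flesh as their tissue label. Group means of R4_RF correlated at 0.945 with Mock flesh, at 0.927 with stage flesh of 30 DAP and at 0.937 with R2_RF. Those of R4_CT correlated at 0.911 with Mock flesh, at 0.901 with stage flesh of 20 DAP and at 0.953 with R2_RF. The tissue make-up of the R4 samples was not tested.

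The change from 20 to 30 DAP differed between rind R4 and flesh at 8912 of 16901 loci (limma interaction, adjusted p under 0.05). Flesh of 20 DAP in this test was CT alone, and how many calls would hold with Mock flesh in its place was not tested. At chr2:2318647-2319172 rind R4 rose from 0.117 to 45.2 FPKM while flesh went from 4.12 ± 0.51 to 0.659 ± 0.633 FPKM (interaction 7.06 ± 0.33 log2, SE, limma adjusted p = 5.44e-08). At chr11:11861823-11863862 rind R4 stood at 12.1 ± 1.83 and 12.4 ± 1.14 FPKM while flesh fell from 249 to 3.92 FPKM (interaction 5.70 ± 0.22, limma adjusted p = 1.15e-08). Mock flesh of 20 DAP held 0.899 ± 0.732 FPKM at that locus, and with that level in place of 249 FPKM flesh would not fall, so this interaction rests on the stage libraries. Rind R4 fell from 14.99 ± 1.31 to 1.51 ± 0.11 FPKM at chr6:26539192-26540035 while flesh rose from 1.10 ± 0.36 to 30.1 ± 1.10 FPKM (interaction -6.57 ± 0.18, limma adjusted p = 6.17e-10). At chr11:1901495-1903825 flesh went from 0.1002 ± 0.1002 to 40.5 ± 1.13 FPKM and rind R4 from 1.11 ± 0.32 to 0.049 ± 0.070 FPKM (interaction -6.25 ± 0.18, limma adjusted p = 8.39e-10), a value that was -10.9 at a pseudocount of 0.1. The interaction was above 0 at 3793 loci and below 0 at 5119, 898 and 1719 of them by at least 1 log2 unit. With median-of-ratios scaling the counts were 4619 and 4630, and 1060 and 1572 by at least 1 log2 unit. A difference between the formats that multiplies a locus by the same factor at both ages cancels only at levels well above 1 FPKM, since 1 was added before the logarithm.

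**Figure D3:**
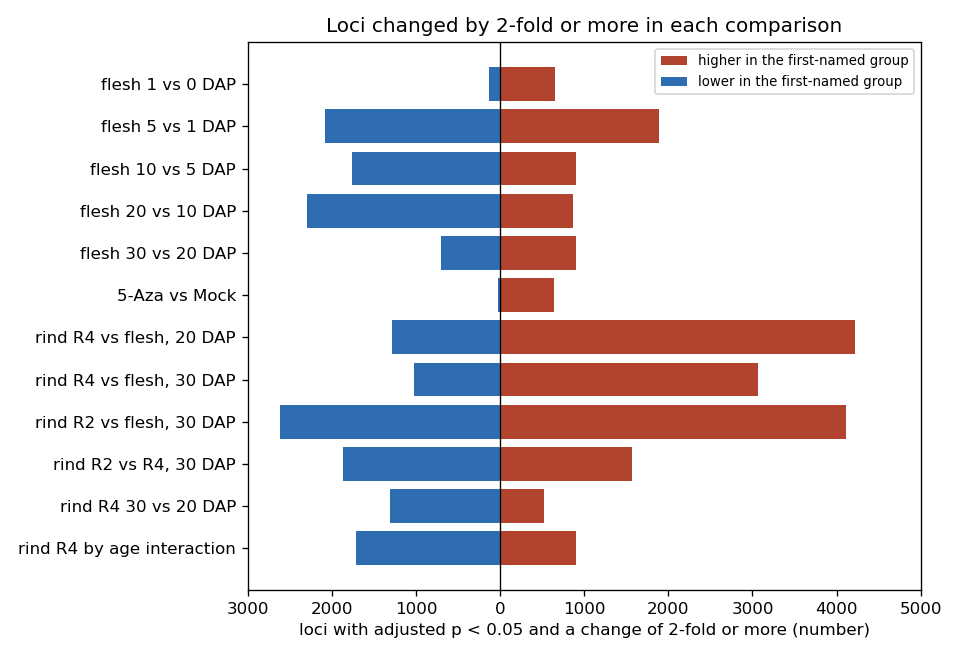
Number of loci with an adjusted p under 0.05 and a change of at least 2-fold, higher (right) and lower (left) in the first-named group, for the 12 comparisons (for the interaction, right means a larger log2 change with age in rind R4 than in flesh). The 5-Aza bar holds 636 loci on the right and 29 on the left, and the longest bars on the right, 4215 and 4114 loci, belong to rind against flesh.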

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

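The tests of sequencing depth at switched-on loci, of the correlation with the 10 to 20 DAP step and its set test, of Mock as the reference for rind, and of other splits of the libraries were chosen only after the results they bear on had been seen. The depth test on switched-on loci did not decide. One on the mean of the 6 libraries was dropped because the rise itself raises that mean, and one on the Mock level took its place, its bounds being written before its value was computed.

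The change with age from 20 to 30 DAP differed between rind R4 and flesh by a direct test of the difference at 8912 loci. Flesh of 20 DAP in this test was CT, which differed from Mock flesh of the same age label at 4130 of 15226 loci by at least 2-fold. How far the 8912 calls rest on the CT libraries was not tested. The 4 loci named for it had interactions of 7.06 at chr2:2318647-2319172, 5.70 at chr11:11861823-11863862, -6.57 at chr6:26539192-26540035 and -6.25 at chr11:1901495-1903825, on the log2 scale. At chr11:11861823-11863862 the fall in flesh depends on the 249 FPKM of the stage libraries at 20 DAP, where Mock flesh held 0.899 FPKM. Rind and flesh also differ in number format, and only a factor that is equal at both ages cancels, at levels well above 1 FPKM.

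After 5_Aza, 636 loci rose and 29 fell by at least 2-fold. Scaling between libraries as the whole cause is argued against by the 544 rises and 48 falls counted with median-of-ratios scaling. A lower depth of the Mock libraries would act at loci low in Mock, and as the whole cause it is argued against by 137 rises and 22 falls at loci of 10 FPKM or more in Mock, over the 5 times set as the bound. That count was not repeated with median-of-ratios scaling, so scaling and depth acting together were not tested. For the 43 loci that were switched on from the floor, 1 reached 10 FPKM in all 3 5_Aza libraries, so lower depth in Mock cannot be told apart from a rise there, because those loci are low. The treatment stays a candidate explanation for the rises at those 137 loci, while depth stays open for risen loci low in Mock, with the hypothesis found and tested on the same data, and differences between fruits or handling were not tested.

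The log2 fold changes of 5_Aza against Mock ran against those of flesh from 10 to 20 DAP, with a Pearson correlation of -0.327 across 14689 loci and no shared library. Of the 493 measured loci that had risen at that step 240 fell and 103 rose after 5_Aza (limma camera, p = 4.41e-13, p = 0.0527 with an estimated correlation), and of the 356 that had fallen 243 rose and 22 fell (p = 2.14e-13, p = 0.0146 with an estimated correlation). Loci near the floor as the whole cause are argued against by a correlation of -0.326 at 7596 loci of 10 FPKM or more. A slower progress of treated fruit may account for the pattern and was not tested against a difference in age or position between Mock and treated fruit, while the next step, from 20 to 30 DAP, gave a correlation of -0.012. With the change of rind R4 from 20 to 30 DAP the Pearson correlation was -0.437 across 15248 loci. Group means of 5_Aza and Mock correlated alike with 10 DAP flesh (0.8550 and 0.8532). With R4_CT they correlated at 0.9210 and 0.9107, with R2_RF at 0.8706 and 0.8605, and with R4_RF at 0.9411 and 0.9447. Slower progress is thus not singled out by these values.

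Rind R4 differed from stage flesh of 20 DAP at 5414 loci by at least 2-fold among 16254 measured against both references, and 48.4% of these calls were found the same way against Mock flesh, which shares the number format of rind. The bounds used were under 10% for a different quantification of the 2 formats as the whole cause and over 50% for its absence. The share lay between them and by itself decided neither way. Both comparisons share the R4_CT libraries, and with unchanged simulated groups their fold changes correlated at 0.605 (measured 0.615) with a covariance of 0.0147 (measured 0.905), while independent lists would share 744 higher and 122 lower loci against 2035 and 585 observed. Within one format R4_CT differed from Mock at 4602 loci by at least 2-fold, a difference that the number format cannot give. This argues against format as the whole cause for the 2035 higher and 585 lower loci called the same way against both references. The rind libraries also form a later block of sample numbers than all flesh libraries. A difference of that block would enter both comparisons through R4_CT, so block and tissue cannot be told apart here. At 143 loci the 2 calls were opposite. Mock and CT, 2 flesh groups of one age label, differed across formats at 4130 loci. How far format enters the calls not shared with Mock thus stays open. At 30 DAP, 0 flesh libraries were in the format of rind, so format and tissue cannot be told apart there.

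Other splits of the same libraries into groups of equal size were counted. In the 4 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and the real split called 12227 loci at 10 against 5 DAP (highest other 2), 12313 at 20 against 10 DAP (highest other 1), 10586 at 30 against 20 DAP (highest other 1) and 6650 for 5_Aza (highest other 1), each being the 1 split with as many. For the 6 stages together, 1 of 100 splits, the real one, gave 16640 loci, and the highest other gave 6399. This argues against a random assignment of these libraries to stages only. Chance differences between fruits stay open, since the replicates may be technical.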

How the results depend on the processing

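The alternatives of rows as deposited, Mock as the reference, other limits for switched-on loci and the set test on the 10 to 20 DAP step were chosen after the results had been seen. Requiring a 2-fold change cut the counts by construction, to 788, 3960, 2666, 3164 and 1610 loci at the 5 steps of the flesh, 665 for 5_Aza, 5496 and 4087 for rind R4 against flesh at 20 and 30 DAP, 6731 for R2 against flesh, 3429 for R2 against R4, 1830 for R4 with age and 2617 for the interaction. With rows as deposited, misaligned libraries entered and counts fell to 10462 for the time course, 734 at 10 against 5 DAP, 1028 at 20 against 10 DAP and 293 at 30 against 20 DAP, and 3 named loci lost their call, chr9:35684709-35685035 with its log2 fold change unchanged at -5.40 (limma adjusted p = 0.1973) and the other two with smaller ones, 1.93 at chr1:7582115-7583400 and -2.43 at chr10:21643784-21644074. The fallen set of the 20 to 30 DAP step after 5_Aza passed only narrowly with 500 loci (p = 0.0459), against 0.3956 with an estimated correlation, 0.194 with 1000 loci, 0.007815 with 200 loci and 0.03744 to 0.06133 with each library left out. The risen set of the 10 to 20 DAP step had p = 0.05268 with an estimated correlation. The 43 switched-on loci became 133 with limits of 0.5 and 1 FPKM, 17 with 0.1 and 2, 24 with exactly 0 in Mock, and 46 to 56 without 1 library. Against Mock, chr9:3608135-3610497 was lower in rind R4 (log2 fold change -2.0948). The cause was not tested for the set, the switched-on or the Mock results.

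Every other total of called loci stayed within 1.5 times of its value, but not every count by direction. With median-of-ratios scaling the falls after 5_Aza went from 2064 to 3479, and those of at least 2-fold from 29 to 48. With rows as deposited the falls at 5 against 1 DAP went from 6353 to 3432. With each library left out, 5_Aza gave 5634 to 6544 loci. Same-numbered libraries showed little joint deviation (correlations of -0.117 to 0.0073 for Mock and 5_Aza, where no library correlated best with its own number, against 0.129 for R2_RF and R4_RF with 2 pairs), and the fit with the replicate number as a block, 6077 loci for 5_Aza and 12190 at 20 against 10 DAP, changed no total by over 1.5 times. Tests of gene lists, protein motifs and published gene identifiers were not run, since loci carry no names here, nor was 5 against 1 DAP without its 1 DAP library. Read depth is unknown, which limits what can be said of loci near 0.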

Other observations

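The tests of loci switched on by 5_Aza, of neighbouring loci and the choice of loci below were made after the main results had been seen.

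Of the loci named, 3 that were higher at 0 DAP than in flesh of 30 DAP were picked out for their levels in rind, without a count over all loci. At chr6:7824799-7825077 the level was 4550 ± 137 FPKM at 0 DAP (SD, n = 3), 10460 at 1 DAP (n = 1), 105 ± 6.04 at 5 DAP and 49.2 ± 1.76 at 30 DAP, against 14103 ± 825 in R4_CT (n = 2), 3082 ± 169 in R4_RF and 34275 ± 488 in R2_RF. At chr2:2318647-2319172 it was 243 FPKM at 0 DAP and 0.659 FPKM in flesh of 30 DAP against 0.117 FPKM in R4_CT, 45.2 FPKM in R4_RF and 328 FPKM in R2_RF. At chr8:21133853-21136470 it was 41.3 FPKM at 0 DAP, 0.024 FPKM in flesh of 30 DAP, 56.03 FPKM in R4_CT, 0.623 FPKM in R4_RF and 38.8 FPKM in R2_RF. Another locus of that kind, chr3:28841637-28842794, was at 492 FPKM at 0 DAP and listed at 0 in all rind libraries. Levels at chr2:2337240-2337639 were 8406 FPKM at 0 DAP, 47.2 FPKM in R4_CT, 3.51 FPKM in R4_RF and 0.297 FPKM in R2_RF. The most abundant locus of 20 DAP flesh, chr10:21559312-21559608, was at 24.1 ± 0.85 FPKM in R2_RF and 6276 ± 1087 in R4_RF. Rind and stage flesh were written in different number formats.

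Mock flesh, with the age label 20 DAP, correlated across loci at 0.928 with stage flesh of 20 DAP and at 0.937 with that of 30 DAP. The locus at chr10:21559312-21559608 stood at 13106 ± 240 FPKM in Mock against 99167 ± 18578 in CT, and chr11:11861823-11863862 at 0.899 ± 0.732 against 249 ± 28.3 FPKM. At chr1:525449-526327 Mock held 79.4 FPKM and 5_Aza 1754 FPKM, against 0.846 to 50.3 FPKM over the flesh stages.

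Of 4261 loci under 0.1 FPKM in all 3 Mock libraries, 43 reached 1 FPKM in all 3 5_Aza libraries, with a median of 2.11 FPKM, and 0 of 3609 loci under 0.1 FPKM in all 5_Aza libraries did so in Mock. Means of 25 of the 43 stayed under 1 FPKM in all the other groups, and 14 (32.6%) reached 1 FPKM in a flesh stage, against 23.4% of the other loci low in Mock, a difference that was not tested. By chromosome they numbered from 0 of 339 low loci on chromosome 8 to 8 of 501 on chromosome 2. One hypothesis was that switched-on loci lie in stretches with few other loci, where silencing by DNA methylation might be denser. The test was negative, with a median of 98 loci within 0.5 Mb against 97 for other loci low in Mock (one-sided circular-shift permutation p = 0.603).

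A further hypothesis was that loci rising after 5_Aza lie next to each other. Among 633 loci on chromosomes that rose by at least 2-fold there were 75 neighbouring pairs, against a median of 26 and a maximum of 43 over 15426 circular shifts (permutation p = 6.48e-05, the smallest the shifts can give, Benjamini-Hochberg adjusted p = 7.41e-05 over 16 tests). The same held in 14 of the 16 tests over 8 comparisons, so such pairs are not confined to the treatment, and whether their excess after 5_Aza differs from that elsewhere was not tested. Neighbouring copies of a gene that share reads, or share regulation, may give such pairs, and sequence to tell these apart was not used here.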
